A study of Mus musculus with 4 samples.

How the data were processed

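RNA was sequenced from 46C cells, a mouse embryonic stem cell line that carries a green fluorescent reporter at the Sox1 locus. All cells were cultured for 24 h in serum with 1 µM PD0325901, an inhibitor of the kinase MEK upstream of ERK. The PD group received no further compound and the PC group also received CID755673, an inhibitor of protein kinase D. Its dose is not given in the sources used here. Each group had 2 libraries, taken from total RNA extracted with Trizol, per the labels' protocols. Samples were placed in their groups by the treatment in the labels. No label says whether the 2 samples of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

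The authors deposited 1 table with a row per gene. Its per-library columns are on a log2 scale. Once the log was undone and 1 subtracted, every value was a whole multiple of a fixed step per library, within a tolerance of 0.001 reads, for 100.0% of values in each library. The deposited log2 values are therefore the log2 of a read count divided by 1 size factor per library, plus 1. The size factors recovered from the steps were 1.0313 and 1.0911 for PD replicates 1 and 2, and 1.207 and 0.8406 for PC replicates 1 and 2. The group columns equal the means of the library columns, and the fold change column equals PC minus PD on the log2 scale. The table also holds p-values and false discovery rates of the authors' own test, per the file headers. The submitters' processing notes name Bowtie 0.12.2 and the mouse build mm9, with no role given. The counting tool, the gene annotation, the strand setting of the counting, the normalization tool and the authors' test are not given in the sources used here.

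The authors' deposited table holds 1593 genes, all with an absolute log2 fold change of at least 1 and a p-value of at most 0.0498. It was thus selected on the comparison it reports. The ratio of false discovery rate to p in the authors' deposited table shows that 31432 genes were tested. The gene with the largest listed p stood at rank 8099, so the listed genes are 19.7% of those that passed the authors' unadjusted threshold of 0.05. Genes outside the table are not analysed here, and a gene that is absent from it may have changed by less than the fold limit.

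The reads recovered on the listed genes were 632042 and 683777 for PD replicates 1 and 2, and 601713 and 433684 for PC replicates 1 and 2. These totals cover the selected genes and are not the depth of the libraries, which is unknown. The median listed gene had 61 and 65 reads in the PD libraries and 56 and 38 in the PC libraries. A gene at 0 reads in a group was given a floor of 3 reads per library, which corresponds to 2.909 and 2.749 normalized reads in the PD libraries and 2.485 and 3.569 in the PC libraries. Such a floor covers counting error only. The 2 libraries of a group were not copies of each other: the chi-square per degree of freedom of their reads was 7.37 over 1448 genes in PD and 7.21 over 1337 genes in PC, with Pearson's r across genes of 0.974 and 0.959. Genes are not independent replicates, so these r values describe the libraries only.

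The plan made before the data were examined named a count test for count tables and limma for normalized values. Because the deposited values are normalized and logged, limma 3.58.1 in R 4.3.3 was fitted to log2(value + 1), with a trended prior for the spread, 2 residual degrees of freedom and no replicate block. Genes needed a mean of at least 1 normalized read over the 4 libraries, which removed none of the listed genes. Benjamini-Hochberg adjustment was made over all 31432 genes tested by the authors, by treating the unlisted genes as having larger p-values than the listed ones, and genes with an adjusted p under 0.05 were called. The treatment of unlisted genes was decided after seeing that the table is a selection. Unlisted genes with small p-values and small fold changes would lower the adjusted p of listed genes, so this adjustment leans towards fewer calls. The spread and its prior, however, came only from genes selected for a small p in these samples. That can make the spread too small and lean towards more calls. Of the 495 calls, 441 had a false discovery rate under 0.05 in the authors' own test. Fold changes are PC minus PD on the log2(value + 1) scale, which understates the change of genes with few reads. For genes at 0 in every library of a group the fitted value is no measure of size, and a lower bound against the floor is given instead.

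The procedure was tested on simulated data drawn for the 1593 listed genes at the real means and size factors, with a dispersion of 0.02. The dispersion was set and not estimated from the data. For PC against PD, limma with Benjamini-Hochberg adjustment recovered 18% of 100 genes changed 2-fold and 79.8% of 99 genes changed 4-fold, and called 0% of the unchanged genes. The real listed genes were all selected for a change, so these shares do not carry over to them. On the same simulated reads voom recovered 23% and 79%.

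Before the data were examined, 29 gene lists with 444 genes were fixed for pluripotency, lineages, signalling, metabolism, stress and chromatin, with 6 lists of markers of other cell types. Of the 444 genes, 441 had a known symbol and 50 were listed. Lists with at least 5 listed members were tested with camera, with a preset inter-gene correlation of 0.01, against the other listed genes, and with fry. Adjustment was over the 4 lists that qualified. Fisher's exact test of each fixed list's split of directions, which the plan did not name, was adjusted over the fixed lists with listed members. Because every listed gene had passed the authors' fold and p limits, these tests compare directions within a selected set. A hypergeometric test of the share of each list in the table, against the 8099 genes, was tried after seeing the data and dropped, because it has to assume that every member of a list was among the 8099, which is unknown.

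Genes were named by a rule fixed before the data were examined. It takes the 12 called genes with the largest rise and the 12 with the largest fall whose PC libraries both lie on the same side of both PD libraries, up to 4 called members of each list by smallest p, and a set of pluripotency, lineage, ERK and protein kinase D genes with their values where listed. The rule asked for a minimum in CPM, which cannot be computed without the depth, so a mean of at least 100 normalized reads was used, chosen after seeing the data. Genes known only by an ID and near-identical family members were counted and not named by size. The rule gave 51 genes, of which 1 is not reported here. Genes named outside it are said to have been chosen after their values were seen.

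Gene identifiers were matched to GENCODE M21, and 1589 of the 1593 matched. That annotation is on another genome build than the mm9 of the processing notes, so no coordinates are given and it served only for names, gene classes, overlaps and neighbour order. Exons of 14 of the 51 named genes overlap exons of another gene in GENCODE M21, for 13 of them on the opposite strand. Without a stated strand setting the reads of such genes cannot be assigned with certainty. Exons of H1fx, Hoxa3, Neurod1, Otx2 and Pigz overlap those of a gene on the same strand, which no strand setting would resolve. For Hoxa3 and Neurod1 that gene is protein-coding (Gm28308 and Cerkl).

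The alternatives tried were other pseudocounts of 0.1 and 5, a minimum mean of 5, an absolute log2 fold change of at least 1, an adjusted p under 0.01, the replicate number as a block, and each library left out in turn. Alternatives chosen after seeing the data were voom on the recovered reads, reads without size factors, adjustment over the listed genes alone and the authors' own false discovery rates. Other scalings and count models, which need a full count table, were not run. The permutation test of neighbouring genes was one-sided, and Fisher's exact tests were two-sided. Other tests used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9.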

Results

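Gene expression was measured by RNA sequencing in 46C mouse embryonic stem cells kept for 24 h in serum with the MEK inhibitor PD0325901 at 1 µM, in 2 libraries without CID755673 (PD) and 2 libraries with it (PC). The comparison asked which genes are regulated by CID755673, a protein kinase D inhibitor, in cells whose MEK is already inhibited. Values are normalized reads, given as mean ± SD over the 2 libraries of a group (n = 2), and cover the 1593 genes of the authors' deposited table, which had been chosen on these same samples for a change of at least 2-fold with a p under 0.05. Reads on these genes ranged from 433684 in PC replicate 2 to 683777 in PD replicate 2, and the full depth is unknown.

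With CID755673, transcripts of the hormone precursor Trh fell from 6232.2 ± 869.5 to 403.6 ± 13.0 normalized reads, and those of the meiotic gatekeeper Stra8 rose from 531.8 ± 84.5 to 6485.6 ± 903.6. The Nodal antagonists Lefty2 and Lefty1, and the DNA methylation cofactor Dnmt3l, were among the abundant transcripts that fell. Of genes of the formative and primed epiblast 5 fell, among them Fgf5, Otx2 and Pou3f1, and 3 targets of ERK fell, while Hoxa3 and Cdx1 rose. As lists, neither kept its camera call with an estimated correlation (adjusted p = 0.28 for the epiblast list and 0.44 for the ERK list). The estimates were -0.13 and 0.79 against the preset of 0.01, so a higher correlation does not account for the lost call of the epiblast list. The estimated setting also raised p for the Hox genes, where the estimate equalled the preset. Of the 1593 listed genes, 613 were higher and 980 lower in PC. limma with Benjamini-Hochberg adjustment over the 31432 genes that had been tested called 495 genes, 179 higher and 316 lower. In the authors' deposited table, of all listed genes 1119 had a false discovery rate under 0.05, 420 higher and 699 lower, and 441 of the limma calls were among them.

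**Figure D1:**
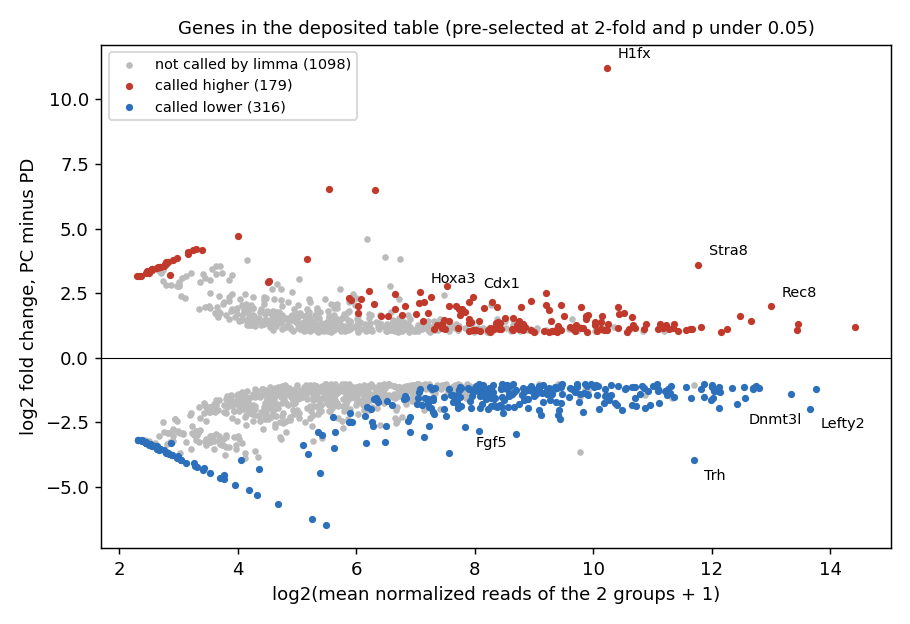
Log2 fold change (PC minus PD) of each of the 1593 listed genes against the log2 of its mean normalized reads plus 1, with genes called by limma in red (179 higher) and blue (316 lower) and the others in grey. The empty band around 0 is the 2-fold selection of the deposited table, and the lines of points at the left edge are genes at 0 reads in every library of a group.

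The called genes had a median of 321.3 normalized reads, and 370 of the 495 had a mean of at least 100. For 83 of the called genes both libraries of a group were at 0 reads, so that their spread rested on the other group, and 412 called genes had reads in both. The number of calls depended on each library. limma called 61 genes without PD replicate 1, 60 without PD replicate 2, and 33 without PC replicate 1 or without PC replicate 2. Of these 1 was higher without either PD library, and all 33 were higher without either PC library. In these fits a lone sample is assumed to vary like the other group, and 1 residual degree of freedom is left. All of these calls were genes at 0 reads in both libraries of a group, so no gene with reads in both groups stayed called with a library left out, although each of the 51 genes of the naming rule kept its direction. In 1588 of the 1593 listed genes both PC libraries lay on 1 side of both PD libraries. Leaving a library out cannot reverse such a gene, so the kept direction was nearly fixed by the selection. At an adjusted p under 0.01, 2 genes were called, and without the size factors 64. Without size factors the PC libraries no longer share a scale.

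The transcript of the linker histone variant H1fx (ENSMUSG00000044927) was at 0 reads in both PD libraries and at 2397.9 ± 3.9 normalized reads in PC, at least 848-fold higher against a floor of 3 reads per library (limma with Benjamini-Hochberg adjustment, adjusted p = 0.0028). It overlaps the antisense gene Gm5577 and the small RNA gene Gm47286 in GENCODE M21, so the origin of its reads is uncertain. Stra8 (ENSMUSG00000029848), which germ cells need to enter meiosis, rose by 3.61 on the log2 scale (SE 0.16, limma with Benjamini-Hochberg adjustment, adjusted p = 0.011), a 12.2-fold ratio of the means. Pigz, a mannosyltransferase of glycosylphosphatidylinositol anchors, rose by 2.79 (SE 0.21) and the homeobox gene Hoxa3 by 2.54 (SE 0.22), from 39.0 ± 7.1 to 229.6 ± 11.8 normalized reads. The dynein light chain gene Dnal1 rose from 176.5 ± 9.6 to 1007.4 ± 31.7 normalized reads, a log2 change of 2.51 (SE 0.11). Cdx1, a caudal-type homeobox gene, rose from 81.0 ± 3.4 to 416.7 ± 55.0, a log2 change of 2.34 (SE 0.16). The kinase gene Cdk15 and the genes Shisa8, Fbxo36, Abcg4, Cfap99 and Ccdc150 completed the 12 largest rises, with log2 changes from 2.34 for Cdk15 to 2.12 for Ccdc150. Exons of Pigz, Hoxa3 and Dnal1 overlap those of other annotated genes.

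Trh, the precursor of thyrotropin-releasing hormone, fell by 3.94 on the log2 scale (SE 0.12, limma with Benjamini-Hochberg adjustment, adjusted p = 0.0069), a 15.4-fold ratio of the means. The glucose transporter gene Slc5a1 fell with a log2 change of -3.07 (SE 0.28), the nucleotide phosphodiesterase gene Enpp3 with -2.95 (SE 0.15) and the complement gene C4b with -2.87 (SE 0.28). Casp14, a caspase of the epidermis, fell from 472.9 ± 101.1 to 66.0 ± 10.9 normalized reads, a log2 change of -2.82 (SE 0.22). Fgf5, a growth factor of the post-implantation epiblast, fell from 394.6 ± 9.6 to 62.1 ± 18.8 normalized reads, a log2 change of -2.68 (SE 0.24). Ms4a10, the integrin gene Itgb2, Enox1, the melanocyte gene Mlana, the ubiquitin ligase gene Fbxo32 and Fgfbp1, a carrier of fibroblast growth factors, completed the 12 largest falls, with log2 changes from -2.64 for Ms4a10 to -2.22 for Fgfbp1. Exons of Enox1 and Fbxo32 overlap those of antisense genes.

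**Figure D2:**
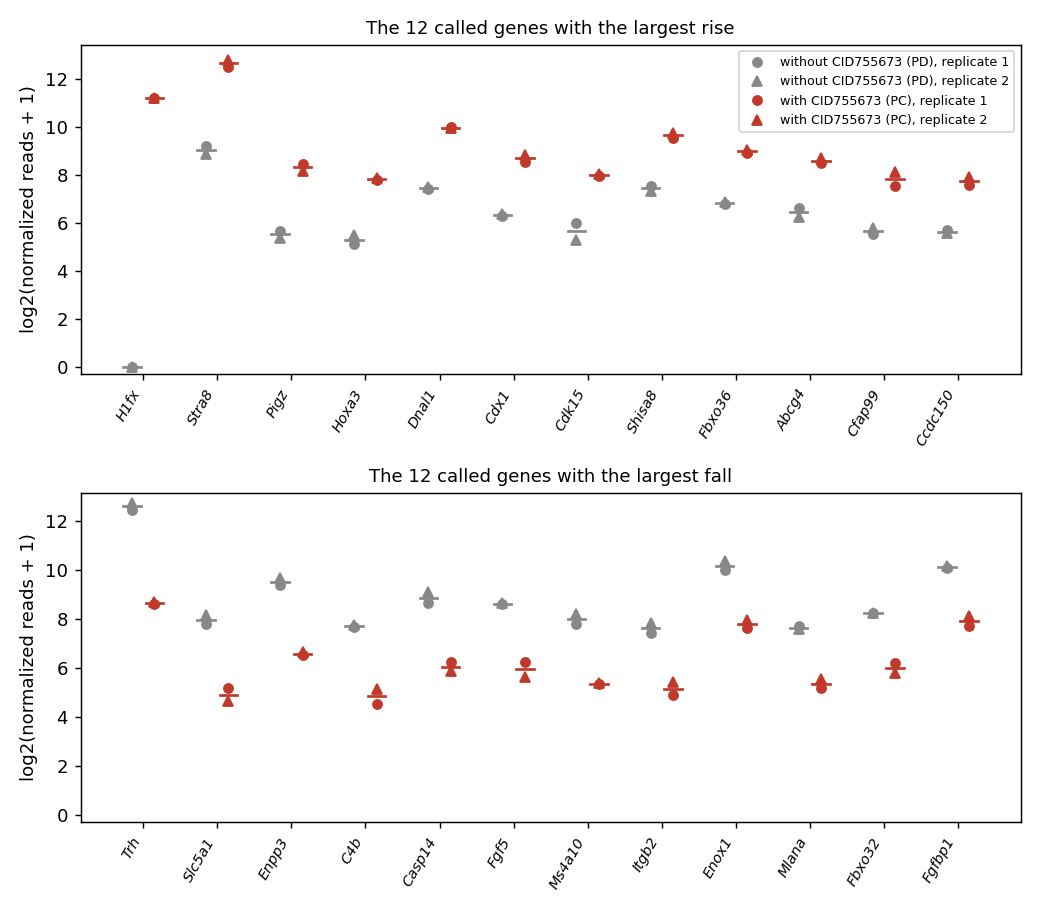
Log2 of normalized reads plus 1 in each of the 4 libraries for the 12 called genes with the largest rise (top) and the 12 with the largest fall (bottom), with PD in grey, PC in red, replicate 1 as circles, replicate 2 as triangles and a line at each group's mean. H1fx sits at 0 in both PD libraries. For each gene shown the PC points lie on 1 side of the PD points, as the naming rule required.

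Among genes of the formative and primed epiblast, the state that follows naive pluripotency, 7 of 13 were listed and all 7 had lower values in PC. Of these, 5 fell over all genes tested and 6 passed when adjusted over the list alone. Because the table was selected on p in these samples, 1536 of all 1593 listed genes passed when adjusted over the listed genes alone, so passing over a list alone is nearly fixed by the selection and is no evidence for any list. This holds for every list below. A gene called over all genes tested also passes over its shorter list by construction. Besides Fgf5, the POU-domain factor Pou3f1 fell from 868.6 ± 11.3 to 214.9 ± 27.5 normalized reads (log2 change -2.02, SE 0.13), the homeobox gene Otx2 from 6014.0 ± 142.6 to 2453.7 ± 157.4 (-1.29, SE 0.09), the DNA methyltransferase gene Dnmt3b from 9170.9 ± 336.5 to 4144.3 ± 96.3 (-1.15, SE 0.08) and the forkhead gene Foxd3, outside the naming rule and chosen after its values were seen, from 1165.7 ± 92.1 to 532.9 ± 8.5 (-1.13, SE 0.11). Lef1 was at 312.8 ± 50.2 in PD and 132.0 ± 35.5 in PC (limma with Benjamini-Hochberg adjustment, adjusted p = 0.13) and Car14 at 118.4 ± 54.7 and 57.0 ± 22.0 (limma with Benjamini-Hochberg adjustment, adjusted p = 1.0), and neither passed. The list was lower than the other listed genes in limma's camera test (Benjamini-Hochberg adjusted p = 0.04), but not with an estimated correlation (adjusted p = 0.28). Of all 1593 listed genes 980 were lower, and the list's split of directions did not pass in Fisher's exact test (Benjamini-Hochberg adjusted p = 0.34). Exons of Otx2 and Pou3f1 overlap those of other annotated genes.

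Of 17 targets of the ERK pathway, which is activated through MEK, 6 were listed, all lower in PC. Of these 3 fell over all genes tested. All 6 passed when adjusted over the list alone, but the selection of the listed genes nearly fixes such a pass. Myc, a growth-promoting transcription factor, fell from 526.1 ± 103.6 to 179.7 ± 15.1 normalized reads (log2 change -1.53, SE 0.18), the feedback inhibitor gene Spry2 from 1423.2 ± 201.1 to 655.9 ± 30.9 (-1.11, SE 0.13) and the ERK phosphatase gene Dusp6 from 939.2 ± 107.8 to 443.0 ± 34.3 (-1.08, SE 0.13). Spry4 was at 144.4 ± 61.5 in PD and 22.4 ± 7.0 in PC and did not pass (limma with Benjamini-Hochberg adjustment, adjusted p = 0.075), nor did Dusp4 and Fosl1. Camera gave an adjusted p of 0.048 for the list (limma, Benjamini-Hochberg), and an adjusted p of 0.44 with an estimated correlation. The list's split of directions did not pass in Fisher's exact test (Benjamini-Hochberg adjusted p = 0.4).

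Of 16 genes of the 2-cell stage, which a small share of embryonic stem cells expresses, 7 were listed, all lower in PC. Of these 4 fell over all genes tested. All 7 passed when adjusted over the list alone, but the selection of the listed genes nearly fixes such a pass. Tmem92 fell from 87.1 ± 2.5 to 11.2 ± 0.6 normalized reads (log2 change -2.86, SE 0.31), Zscan4a from 243.8 ± 12.9 to 63.1 ± 3.4 (-1.93, SE 0.17), Zscan4f from 399.5 ± 1.4 to 142.9 ± 6.5 (-1.48, SE 0.13) and Zscan4c from 363.7 ± 21.8 to 132.4 ± 31.4 (-1.47, SE 0.20). Every listed member apart from Tmem92 was a Zscan4 gene. The Zscan4 genes are near-identical copies, so their reads may be shared and their single values are uncertain. They are not independent members, so the count of lower genes and the camera p overstate the evidence for the list. The camera adjusted p was 0.04 (limma, Benjamini-Hochberg), and the adjusted p was 0.28 with an estimated correlation. The list's split of directions did not pass in Fisher's exact test (Benjamini-Hochberg adjusted p = 0.34). For both the epiblast and the 2-cell-stage lists the camera adjusted p was 0.064 without PD replicate 1, 0.06 without PD replicate 2, 0.058 without PC replicate 1 and 0.031 without PC replicate 2, and for the ERK list it was 0.064, 0.06, 0.12 and 0.11 in the same order.

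**Figure D3:**
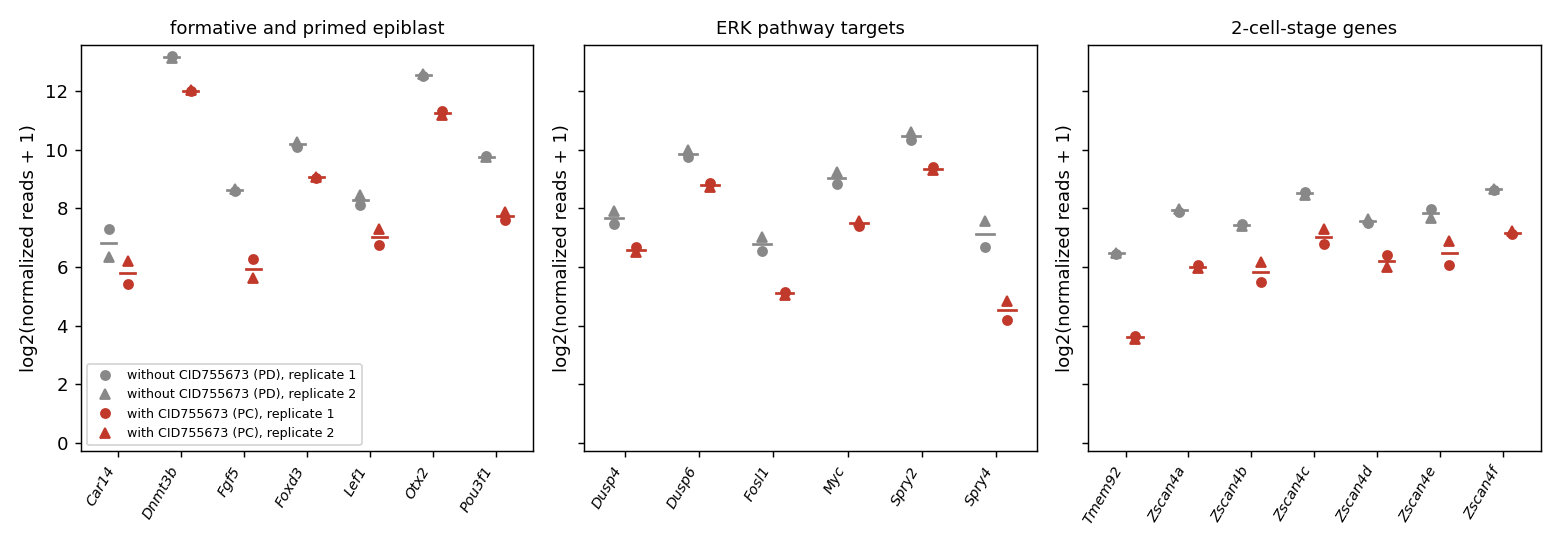
Log2 of normalized reads plus 1 in each of the 4 libraries for the listed members of 3 fixed gene lists, with PD in grey, PC in red, replicate 1 as circles, replicate 2 as triangles and a line at each group's mean. Every listed member of the 3 lists has a lower mean in PC, from Dnmt3b, which fell from 9170.9 to 4144.3 normalized reads, to Car14, which did not pass the test.

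Of 14 general pluripotency genes 3 were listed. All 3 fell, and so passed by construction when adjusted over the list alone. Dnmt3l fell from 8604.2 ± 343.1 to 2472.0 ± 70.6 normalized reads (log2 change -1.80, SE 0.08), the chromatin factor Utf1 from 7052.3 ± 576.9 to 1840.4 ± 75.5 (-1.94, SE 0.10) and the RNA-binding protein gene Lin28a from 8206.3 ± 185.4 to 3780.7 ± 171.8 (-1.12, SE 0.08). Among 10 genes of the DNA methylation machinery the listed ones were Dnmt3l and Dnmt3b, and both passed when adjusted over the list alone. Exons of Dnmt3l overlap those of Aire on the other strand, and exons of Lin28a overlap those of another transcript. Of 17 naive pluripotency genes, 15 targets of LIF and STAT3, and 14 genes of protein kinase D and its substrates, 0 were listed. Nanog, Klf4, Esrrb, Tfcp2l1, Prkd1, Prkd2, Prkd3, Pou5f1 and Sox2 are therefore not analysed here.

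Of 14 targets of BMP and Nodal signalling 3 were listed, and all 3 passed over all genes tested and when adjusted over the list alone. Lefty2 fell from 20546.3 ± 74.6 to 5296.6 ± 414.6 normalized reads (log2 change -1.96, SE 0.09) and Lefty1 from 14985.5 ± 759.6 to 5652.9 ± 235.7 (-1.41, SE 0.09). Id2, a target of BMP that inhibits differentiation factors, rose from 2057.2 ± 121.4 to 4434.4 ± 162.2 (1.11, SE 0.09). Of 16 Wnt targets 3 were listed, and Cdx1 rose while Lef1 and Dkk1 did not pass over all genes tested; 2 passed when adjusted over the list alone.

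Of 20 endoderm genes 3 were listed, and 2 passed both over all genes tested and when adjusted over the list alone: Foxa1 rose from 193.3 ± 7.7 to 490.6 ± 86.8 normalized reads (log2 change 1.33, SE 0.16) and Gata6 from 188.6 ± 6.2 to 423.9 ± 61.7 (1.16, SE 0.15), while Sox17 was at 26.9 ± 1.7 in PD and 65.1 ± 29.8 in PC and did not pass. With a pseudocount of 0.1 neither Foxa1 nor Gata6 passed (limma with Benjamini-Hochberg adjustment, adjusted p = 0.055 and 0.062). Of the genes of other lineages, the neuronal factor Neurod1 fell from 1098.5 ± 62.8 to 272.1 ± 3.0 (-2.01, SE 0.11), as 1 of 15 neuroectoderm genes, and passed when adjusted over the list alone. The mesodermal homeobox gene Evx1 was at 29.1 ± 5.5 in PD and at 0 reads in both PC libraries, at least 9.61-fold lower. It was 1 of 2 listed among 18 primitive streak and mesoderm genes, and passed also when adjusted over the list alone, and the other, Kdr, did not pass. The trophectoderm gene Gata3, 1 of 12, was at 382.1 ± 2.8 in PD and 164.0 ± 43.5 in PC and passed only when adjusted over the list alone. The brachyury gene T and Sox1 are not analysed here. Exons of Evx1, Neurod1 and Gata6 overlap those of other annotated genes.

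Of 16 developmental regulators held by PRC2 in embryonic stem cells 7 were listed, 4 with higher and 3 with lower values. Of these 1 passed over all genes tested. All 7 passed when adjusted over the list alone, but the selection of the listed genes nearly fixes such a pass. The T-box gene Tbx5, chosen after its values were seen, was at 16.4 ± 4.0 in PD and 53.7 ± 3.7 in PC and did not pass over all genes tested (limma with Benjamini-Hochberg adjustment, adjusted p = 0.18). The list did not stand apart from the other listed genes in camera (limma, Benjamini-Hochberg adjusted p = 0.23).

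Smaller lists held few listed genes. The desaturase gene Scd1 was the 1 listed member of 13 fatty acid synthesis genes and rose from 3108.9 ± 242.6 to 6686.0 ± 349.3 normalized reads (log2 change 1.11, SE 0.10), also when adjusted over the list alone. Among 17 genes of extracellular matrix and adhesion, the galectin gene Lgals1 rose from 2215.4 ± 93.7 to 5006.5 ± 307.0 (1.18, SE 0.09) and the urokinase receptor gene Plaur fell from 555.4 ± 99.8 to 146.7 ± 2.2 (-1.90, SE 0.17), and both passed when adjusted over the list alone. The kinase inhibitor gene Cdkn2b, 1 of 20 cell cycle genes, fell by 1.21 on the log2 scale (SE 0.15) and passed when adjusted over the list alone. Of 14 genes of the AhR and NRF2 xenobiotic response 3 were listed; Aldh3a1 fell by 1.05 (SE 0.12), Cyp1b1 and Gclm did not pass over all genes tested, and 2 of the 3 passed when adjusted over the list alone. The p53 target Fas, 1 of 15, was lower in PC and did not pass either way. The germline gene Tex101, 1 of 15, was also lower and passed only when adjusted over the list alone. Of the lists for FOXO targets, cholesterol biosynthesis, glycolysis, hypoxia, oxidative phosphorylation, the unfolded protein response, heat shock, and SRF and YAP targets, 0 genes were listed, and their levels are not analysed here.

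Among markers of other cell types that the cultures could hold, 2 of 10 extra-embryonic endoderm markers were listed, both with higher values, Gata6 and Sox17, of which 1 passed. Listed markers of other types all had lower values in PC: Col3a1 of fibroblasts, Gata3 of trophoblast, Myh6, Myh7 and Tnnt2 of muscle, and Tek of endothelium, chosen after their values were seen. Of these Tek fell from 3362.7 ± 117.7 to 1388.4 ± 104.5 normalized reads (log2 change -1.28, SE 0.10) and Myh7 from 216.0 ± 59.3 to 59.3 ± 6.4 (-1.83, SE 0.25), and the others did not pass. When adjusted over the list alone, 1 endoderm, 1 trophoblast, 3 muscle, 1 endothelial and 0 fibroblast markers passed. Of 6 neural progenitor markers 0 were listed.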

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

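Tests named here as voom, reads without size factors, adjustment over the listed genes alone and the authors' false discovery rates were chosen after the data were seen. No named gene or tested list reversed its direction under the alternatives run, which for named genes the selection nearly fixed. The balance of higher and lower calls did reverse with a PC library left out. Against 495 called genes (179 higher, 316 lower), limma called 1176 (435 and 741) with the replicate block. Same-numbered samples did not deviate together (r = -0.003 over 597 genes with a mean of at least 100 normalized reads). The genes were selected on p and the labels state no pairing, so whether the numbers pair the samples stays open. Without 1 library it called between 33 and 61 genes (higher 1 to 33, lower 0 to 60): 1 higher and 60 or 59 lower without PD replicate 1 or 2, and 33 higher and 0 lower without either PC replicate, with 979, 959, 1231 and 1185 genes at an unadjusted p under 0.05 without PD replicates 1 and 2 and PC replicates 1 and 2, and fewer samples are the cause by construction. All 61, 60, 33 and 33 calls were genes at 0 reads in both libraries of a group, where limma finds no spread in that group, so the direction largely follows from which group kept both libraries. Counts were 1536 (581 and 955) when adjusted over the listed genes alone, which tests fewer genes, 64 (24 and 40) from reads without size factors, where the median fold change moved by -0.07 on the log2 scale, 2 (1 and 1) at an adjusted p under 0.01, and 1119 (420 and 699) at the authors' deposited FDR under 0.05; for the size factors and the authors' test the cause was not tested. Counts within 1.5 times of 495 were 417 and 582 with pseudocounts of 0.1 and 5, 471 with a mean of at least 5, 661 with voom, which called all 495, and 703 at the authors' FDR under 0.001. The fold minimum and the filter on low values removed no gene, so they test nothing.

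With an estimated inter-gene correlation the camera adjusted p was 0.28 for the formative and the 2-cell-stage lists and 0.44 for the ERK list. The estimates were -0.13, -0.1 and 0.79 in that order, against the preset of 0.01. A higher correlation therefore does not account for the lost calls of the formative and 2-cell-stage lists. For the Hox genes, a list added later, the estimate equalled the preset at 0.01, yet the camera p went from 8.7e-05 to 0.06. The estimated setting thus raises p even at an unchanged correlation. A call lost under it is not by itself evidence of correlated members. For the PRC2 list, fry gave an adjusted p of 0.037 (directional) and 0.0022 (mixed), but every listed gene had been selected for a change in these samples, so a test against no change says nothing of the list. Without 1 library the camera adjusted p lay between 0.031 and 0.064 for the formative and 2-cell-stage lists, between 0.06 and 0.12 for ERK and between 0.2 and 0.42 for PRC2, and the cause was not tested. The replicate block changed no list call. Of the 51 named genes, 48 lost their call without either PD library, 50 without either PC library, 45 without size factors and 6 with a pseudocount of 0.1. Their folds moved little: with a library left out all 204 values kept their sign, with a median difference of 0.07 and a largest of 0.45 on the log2 scale (Spry4), and without size factors the largest was 0.08. The selection nearly fixed the kept signs, so they are no added evidence. The 6 that lost their call with a pseudocount of 0.1 were Cdk15, Cfap99, Foxa1, Gata6, Dusp6 and Zscan4c. Spry4 gained a call with the block, a pseudocount of 5, the listed genes alone and the authors' FDR. Not run were other scalings and count models, which need the full count table. At 2-fold the simulated recovery was 18%, which does not carry over to the listed genes, all selected for a change.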

Other observations

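All tests in this part were chosen after the data were seen, except the test of name families among neighbouring genes, whose prediction was written before its result. Some genes of meiosis rose beside Stra8. In a list of 20 genes of meiosis and of the repressor complex PRC1.6, drawn up once the table had been examined, 5 were listed and all 5 rose. The meiotic cohesin gene Rec8 rose from 3278.4 ± 163.4 to 13047.2 ± 421.1 normalized reads (log2 change 1.99, SE 0.08), Meioc from 1616.7 ± 98.5 to 3608.0 ± 27.0 (1.16, SE 0.09) and the mismatch repair homolog Msh5 from 102.5 ± 14.1 to 352.0 ± 10.3 (1.78, SE 0.16), with Dmc1 at a log2 change of 1.28. Camera gave p = 0.00019 for the list and p = 0.098 with an estimated correlation. Its members were chosen on these samples and are not independent evidence of its direction. The list of 15 germline genes fixed beforehand had 1 listed member, Tex101, which was lower in PC. The gonadal regulator Dmrt1 rose from 1288.8 ± 13.9 to 3210.8 ± 90.8 (1.32, SE 0.08).

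Other abundant genes, picked after their values were seen, were also called by limma. The phosphatase gene Dusp9 rose from 13144.8 ± 571.0 to 30505.9 ± 1425.3 normalized reads (log2 change 1.21, SE 0.09), while Dusp6 of the same family fell. The GTPase gene Rac1 rose from 2820.1 ± 276.0 to 8610.2 ± 28.4 (1.61, SE 0.10) and the kinase gene Abl1 from 3565.3 ± 208.8 to 9493.2 ± 465.8 (1.41, SE 0.09). The p53 relative Trp73 fell from 2985.2 ± 169.4 to 781.1 ± 17.4 (-1.93, SE 0.09) and the growth factor gene Fgf15 from 2289.1 ± 32.0 to 567.8 ± 18.0 (-2.01, SE 0.09). The threonine dehydrogenase gene Tdh, high in mouse embryonic stem cells, fell from 19382.9 ± 189.0 to 8522.1 ± 268.9 (-1.19, SE 0.08).

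H1fx was at 0 reads in both PD libraries and at 2397.9 normalized reads in PC. Of the 94 genes at 0 reads in every library of a group, 0 apart from H1fx reached a mean of 100 in the other. That minimum was set after the next highest were seen, Gm6361 at 91.7 in PC and Gm17208 at 88.5 in PD, so it stays open whether the 2 groups were counted against different gene annotations across the table. It may also be that reads of H1fx were given to an overlapping annotated gene in the PD libraries. Of the annotated genes that overlap H1fx, 0 have values in the table, and genes outside it are not analysed here, so this cannot be told apart from a change in expression. An effect of CID755673 on H1fx itself stays open as a hypothesis.

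Of 39 Hox genes 10 were listed, and all 10 had higher values in PC, from 6 genes of the Hoxa cluster and 4 of the others. Of these 4 passed the limma test, Hoxa3, Hoxa7 and Hoxb3 among them, and 6 did not. Fisher's exact test of the split against the other listed genes gave p = 6.8e-05, and camera p = 8.7e-05, or p = 0.06 with the correlation estimated, at 0.01. The Hox genes were chosen because they showed the pattern, and genes of a cluster are not independent, so chance direction stays open. Of 9 listed markers of lineages other than endoderm 0 were higher, which allows a pooled share of at most 33.6% (upper 95% exact limit). With 0 listed markers of neural progenitors and few of each other lineage, cells of a single lineage stay open, as do cells of the endoderm. A response like that to retinoic acid may also be a candidate explanation: 4 listed retinoic acid targets outside the Hox clusters, Cdx1, Stra6, Stra8 and Tgm2, were higher, but they were picked after the data were seen.

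Listed genes that lie close together tended to change in the same direction. Of 276 pairs of listed genes with at most 3 annotated genes between them in GENCODE M21, 219 (79.3%) had the same direction, against 52.7% expected and at most 64.1% in 10000 permutations of the directions (one-sided permutation p = 0.0001, the smallest they can give). Reads shared by overlapping genes are argued against as the whole cause, since 79.3% of the 232 pairs without overlap had the same direction, and families of similar genes side by side likewise, with 77.0% of the 243 pairs without them. Regulation of neighbouring genes as a domain, and transcription that reads through from a gene into the next, may each give such pairs and were not tested.

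Of 55 listed processed pseudogenes 8 were higher and 47 lower (Fisher's exact test against the other listed genes, Benjamini-Hochberg adjusted p = 0.0005), and all 10 listed transcripts from bidirectional promoters were higher (adjusted p = 0.0005). On chromosome 14, 9 of 57 listed genes were higher (adjusted p = 0.0049), on chromosome 5, 52 of 99 (0.038) and on chromosome 17, 36 of 65 (0.039). Among listed genes with a false discovery rate under 0.05 in the authors' deposited table all 3 splits passed, with 7 of 46 higher on chromosome 14 (adjusted p = 0.0099), 41 of 72 on chromosome 5 (0.0099) and 29 of 49 on chromosome 17 (0.015). Among named protein-coding genes none of the 3 passed, with 7 of 42 higher on chromosome 14 (adjusted p = 0.1), 35 of 70 on chromosome 5 (0.2) and 25 of 49 on chromosome 17 (0.24). Neighbouring genes are not independent, so these p-values are too small. Of 56 KEGG pathways with at least 10 listed genes, 0 had a split of directions past an adjusted p of 0.05 in Fisher's exact test and 7 were under 0.05 unadjusted.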
